A study of Mus musculus with 2 samples.

How the data were processed

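Gene expression was measured on Illumina bead arrays in tibialis anterior muscle, a lower leg muscle, of C57/BL6 mice injected under the skin at 10 days of age with vehicle or with DHT, read here as dihydrotestosterone, a potent androgen. Muscle was taken 24 h after the injection. Per the labels, RNA was extracted with Trizol and 0.55 µg of total RNA was amplified into biotin-labelled cRNA. The series held 1 array per group, so 2 arrays in all. The labels do not say whether an array held RNA of a single animal or of several, nor the sex or litter of the animals, and they date no array.

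The deposited signal intensity is the brightness of each probe on a linear scale, not normalized between arrays and without background subtraction, as its values show. Beside it stands a detection p-value per probe and array, deposited by the authors and headed as such in the table, which compares the probe with the array's background. The deposited series values are on a log2 scale: both columns held the same sorted values to within 0.000318, had a median of 7.43, and lay within 0.00065451 of a quantile normalization of the log2 signals, with no centring of genes. The submitters' processing notes name GenomeStudio 2011.1. Its role, and any genome build, are not given in the sources used here, so no coordinates are printed.

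Each array had 25697 probes. The total signal was 2.99e+07 on the vehicle array and 2.65e+07 on the DHT array, with medians of 177 and 168 and lowest signals of 109 and 106. A detection p under 0.01 was taken as detected, which held for 11949 probes (46.5%) on the vehicle array and 11734 (45.7%) on the DHT array. On both arrays 11186 probes were detected, on 1 array 1311 and on neither 13200. Signals above 40000, near the top of the scale, were reached by 88 probes on the vehicle array and 75 on the DHT array, 68 of them on both. Differences of probes above 40000 on both arrays are compressed. Those of probes above it on 1 array can be too, so their folds may be too small.

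Probes were named through the platform annotation supplied for the deposited values, which can be old. A single symbol was given for 23978 probes, several for 0 and none for 1719. Of the Entrez identifiers, 23962 matched a mouse gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. The named probes covered 16593 symbols. Probes of multigene families, among them the H2ac histones, the Hba and Hbb globins, Amd2, Gbp3, Lyz1, Apoc1 and Ces1d, can bind transcripts of near-identical copies, and their values are uncertain for that reason.

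Background was corrected, an offset of 16 added, and values quantile normalized and put on the log2 scale with limma's neqc (limma 3.58.1, R 4.3.3), with the background inferred from the detection p-values. Genes were kept if a probe was detected on at least 1 array, and a gene's value came from its detected probe with the highest mean. Among the list members, detected probes of a gene disagreed in sign, with a gap well beyond the probe-to-probe SD of 0.25, for Abcc9, Ccn1, Coro1a, Epn2, Hspd1, Mbp, Rpl23, Rplp0, Rps19, Tef, Tk1, Tpm3 and Traf6. Smaller gaps of opposite sign, such as that of Ncstn, are not listed. This gave 8815 named genes, 7971 detected on both arrays, 512 on the vehicle array alone and 332 on the DHT array alone. Differences are DHT minus vehicle on the log2 scale, and folds are brighter over dimmer. A gene not well above background on 1 array has only a bound, written as at least N-fold, against the lowest signal among detected probes of that array or the gene's own, whichever was higher. These bounds are bounds on the background-corrected scale alone: the uncorrected fold, without background correction, can be smaller than the bound, and is given beside it where the bound is over 1.5 times larger. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

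With 1 array per group there is no residual spread, so no test, p-value or standard error between the conditions is given, and genes are counted at 1.5-fold and at 2-fold. For each of 35 gene lists fixed before the data were examined, the median difference of its detected members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 95% of those medians, a description of these 2 arrays. The lists covered Notch ligands, Notch receptors and targets, satellite cell, myogenic, neonatal, cell cycle, slow and fast fibre, androgen, glucocorticoid, atrophy, growth factor, polyamine, clock, immediate early, heat shock, interferon, ribosomal, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol, matrix and sex chromosome genes, and markers of fibroblasts, macrophages, neutrophils, lymphocytes, erythroid cells, endothelium, pericytes, adipocytes, Schwann cells, tendon and skin. Another 6 lists were written after the data were seen: imprinted growth, lymph node and lymphocyte, liver and plasma protein, replication-dependent histone, and unfused or recently fused myofibre genes, and the lymphocyte genes whose values had not been looked at.

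The genes named were set by a rule written before the data were examined: the 12 largest differences in each direction among genes detected on both arrays, the 5 largest bounds in each direction, up to 4 members of a list with the largest differences, and 29 genes fixed by name, 1 of which is not reported here. Any other gene named was chosen after its values were seen.

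Alternatives fixed in advance were no background correction, median scaling or cyclic loess in place of quantile normalization, an offset of 50, detection on both arrays, a detection p under 0.05, the mean of a gene's probes, the deposited log2 values, the 2-fold threshold, and random lists not matched on expression. Leaving out the probes above 40000 on both arrays was added after the data were seen.

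The steps were tested on simulated arrays of 25697 probes with assumed noise. Of 50 dim genes with a true 2-fold difference, 98% passed 1.5-fold, with a median log2 difference of 0.87 against 0.46 without background correction. For 50 dim genes with a true 4-fold difference these medians were 1.82 and 1.16. For bright genes they were 0.95 and 0.85 at 2-fold, and 1.94 and 1.72 at 4-fold. Of 12703 unchanged probes, 5.88% passed 1.5-fold. Among lists of 15 genes, 4.75% of 400 unshifted lists and 96% of 100 lists shifted by 0.5 were called apart. The gene differences of these lists were drawn independently of each other.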

Results

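The series asks how sex hormones act on juvenile muscle, under a title about the adult reserve of muscle stem cells at puberty. Its arrays compare tibialis anterior muscle of 10-day-old C57/BL6 mice 24 h after an injection of DHT with muscle after vehicle. Each group had 1 array and no replicates, so every difference below describes these 2 arrays and carries no error between animals. Within the arrays, probes of the same gene differed in their log2 difference with an SD of 0.25 over 1967 genes. Background probes, chosen for a detection p above 0.05 on both arrays, had an SD of 0.20 over 11395 probes. Neither SD was taken over dim detected genes alone. Among named probes with a vehicle signal within 10% of that of the dim gene Mib1, most differences lay between -1.24 and 1.32, real ones included. The log2 signals of all probes correlated between the arrays with a Pearson r of 0.98 across probes, which are not independent replicates.

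On the DHT array the enzymes Inmt, a methyltransferase, and Cdo1, which starts cysteine breakdown, were higher by 15.4-fold (10.0-fold uncorrected) and 9.47-fold (6.92-fold uncorrected). Prc1, a protein of the dividing cell's midzone, was 26.7-fold lower (10.3-fold uncorrected), and Pdk4, a kinase that restrains glucose oxidation, 18.6-fold lower. Myh8, the perinatal myosin heavy chain, was 17.6-fold lower, with a vehicle signal of 54364, near the top of the scale. Of 8815 named genes, 1180 were at least 1.5-fold higher and 1394 at least 1.5-fold lower, together 2574 or 29.2%. At 2-fold the counts were 406 and 554. Among genes detected on both arrays, 957 were higher and 1068 lower at 1.5-fold.

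The remaining genes with the largest positive differences were Odf3l2 (log2 difference 3.27), Gm5111 (3.20), the mitochondrial carrier Slc25a25 (3.16), the lipase Ces1d (2.97), haptoglobin Hp (2.96), the lipolysis inhibitor G0s2 (2.84), the Notch effector Heyl (2.80), Serpina3n (2.79), Apoc1 (2.79) and Mrap (2.74). Those with the largest negative differences were the H2A histone genes H2ac22 (-4.63), H2ac10 (-4.48), H2ac24 (-4.17) and H2ac12 (-4.03), the neutrophil granule gene Ltf (-4.33), the apelin receptor Aplnr (-4.03), the eosinophil granule gene Prg2 (-3.99), Angptl4 (-3.62), an inhibitor of lipoprotein lipase, and Stfa1 (-3.55). Glycam1, a mucin made by lymph node venules, was not well above background on the vehicle array and at least 62.6-fold higher on the DHT array on the background-corrected scale, where the uncorrected fold was 22.2. On that scale Cyp2e1 was at least 37.4-fold higher (11.3-fold uncorrected), Tmem87a 19.3-fold (6.87-fold), Gsta3 11.4-fold (4.26-fold) and Cd209b 8.52-fold (3.83-fold). In the other direction, Dstn was at least 68.5-fold lower on that scale (23.6-fold uncorrected), though its second probe was detected on neither array. Pbk was at least 14.6-fold lower (5.40-fold uncorrected), Prnd 13.5-fold (4.78-fold), H2ac15 11.9-fold (4.16-fold) and Cdc20 11.3-fold (4.17-fold). Every at-least fold given for other genes is likewise a bound on the background-corrected scale.

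The counts and the folds of dim genes depended on the background correction. Without it, 564 genes were higher and 704 lower at 1.5-fold, and the folds of 16 of the 24 genes with the largest differences were over 1.5 times smaller, with all 24 in the same direction at 2.70-fold or more.

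**Figure D1:**
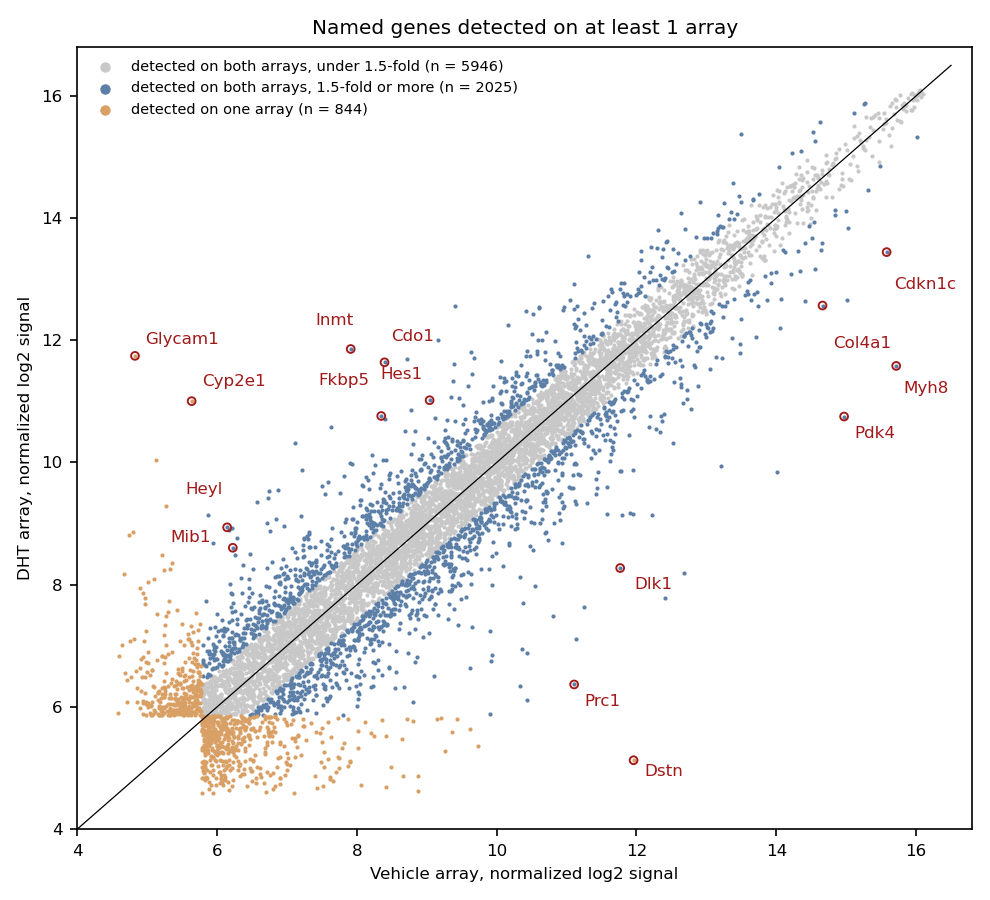
Normalized log2 signal of the 8815 named genes on the vehicle array (horizontal axis) and the DHT array (vertical axis), 1 point per gene, with the line of equal signal. Grey points are genes detected on both arrays under 1.5-fold, blue points those at 1.5-fold or more, and orange points genes detected on 1 array, whose folds are bounds. Inmt and Glycam1 lie far above the line, and Prc1 and Myh8 far below it.

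The first group of genes bears on Notch signalling, through which muscle stem cells, the satellite cells, are kept quiescent. Mib1, the ubiquitin ligase that a signal-sending cell needs to activate its Notch ligands, was 5.20-fold higher on the DHT array (log2 difference 2.38, probe ILMN_2933834), with deposited signals of 213 on the vehicle array and 471 on the DHT array. The Notch effectors Heyl (6.94-fold, probe ILMN_1213139), Hey1 (5.54-fold, probe ILMN_2690596) and Hes1 (3.94-fold, probe ILMN_1247691) were also higher, while the Notch target Nrarp (-0.92) and the target collagens Col5a1 (-1.33), Col5a3 (-0.91) and Col6a1 (-1.39) were lower. Collagen and matrix genes were lower as a group, 20 of 24 measured, with a median of -1.25. The lower target collagens therefore do not speak on Notch signalling by themselves. Notch receptors were lower, with log2 differences of -0.97 for Notch1, -1.44 for Notch3 and -1.11 for Notch4. The non-canonical ligand Dlk1, an imprinted gene, was 11.3-fold lower. Mib1, Hey1 and Heyl were dim on the vehicle array, and without background correction their folds were 2.43, 2.59 and 2.95.

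The ligand list as a whole did not move with Mib1. Its 12 measured members had a median of -0.23, inside the central 95% of random lists, with 1 higher and 3 lower at 1.5-fold, or 1 lower among those detected on both arrays. The ligands Dll1 (-0.19) and Jag2 (0.16) and the related ligase Mib2 (0.18) differed by less than the probe-to-probe SD. That SD was taken over probes of any brightness, and differences of dim probes, real ones included, spread more widely. Dll1 had deposited signals of 258 on the vehicle array and 218 on the DHT array, and Jag2 201 and 192. These lay near the lowest detected signals, 190 and 180, so a change of either ligand could be missed. Jag1 and Dner were not well above background on the DHT array and were at least 1.29-fold and 2.61-fold lower, the latter 1.51-fold uncorrected. The 19 receptors, cofactors and targets had a median of -0.11, also inside the random range, with 3 higher and 8 lower, the target collagens among the latter. Calcr, a target that marks quiescent satellite cells, was at least 1.81-fold lower. Dll4, Notch2 and Rbpj were detected on neither array.

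Genes of satellite cells and quiescence were lower on the DHT array. The 12 measured members had a median of -0.81, where the central 95% of random lists ran from -0.39 to 0.30, and 8 were lower and 0 higher at 1.5-fold. The cell cycle inhibitor Cdkn1c, another imprinted gene, was 4.40-fold lower (-2.14), the syndecan Sdc3 2.39-fold (-1.26), and the adhesion molecule Ncam1 2.25-fold (-1.17). Without background correction 5 of the 12 were lower at that threshold. Some members also belong to other groups that were lower: Ncam1 to the neonatal list, whose median was -0.82, and Rgs5 (-0.18) to the pericyte list, at -0.54, while Cd34 (-0.79) is also made by endothelium, whose markers had a median of -0.78. The satellite cell transcription factors Pax7 and Myf5 were detected on neither array, so their levels were not compared.

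Several genes of myogenic commitment, fusion and the immature fibre were lower too. The commitment factor Myod1 was 2.20-fold higher (1.14), while Myog, which acts later in differentiation, was 2.89-fold lower (-1.53, with its other probe at -0.60), the fetal acetylcholine receptor subunit Chrng 3.34-fold lower (-1.74, and 1.89-fold uncorrected), and the fusion protein gene Mymk at least 4.59-fold lower (2.65-fold uncorrected). The 15 myogenic genes had a median of -0.49, with 6 lower and 1 higher. The 13 neonatal and denervation genes, which share Myh8, Chrng, Myog and Ncam1 with that list, had a median of -0.82, below all 10000 random lists, with 8 lower and 1 higher. Both Myh8 probes were low, at -4.14 and -4.77.

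Among contractile genes, the slow fibre list was lower and the fast fibre list was not. The 10 slow fibre genes had a median of -0.47, with 4 lower and 0 higher, led by the calcium store protein Casq2 (-1.60), the slow myosin Myh7 (-1.21, 1.44-fold uncorrected), slow troponin I, Tnni1 (-0.83), and Myl3 (-0.63). The 16 fast fibre genes had a median of 0.06, with Pygm at 0.68, Myoz1 at 0.52, Myh1 at -0.47 and Myh4 at 0.41. Of these 16 genes, 9 were above 40000 on both arrays, which compresses their differences. Without such probes the fast fibre median was 0.33 and stood apart.

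Cell cycle genes were lower on the DHT array. Top2a, which untangles replicated DNA, the mitotic activator Cdc20, the mitotic kinase Cdk1 and the survivin gene Birc5 were detected on the vehicle array and not well above background on the DHT array. Their folds were at least 8.11, 11.3, 9.75 and 7.24 on the background-corrected scale, and 4.15, 4.17, 3.54 and 2.82 uncorrected, all lower. The 19 measured members had a median of -1.87, below all 10000 random lists, with 14 lower and 0 higher at 1.5-fold. With the 8 genes detected on 1 array placed at their bounds the median was -1.04. It was -0.82 without background correction and -0.64 for the 11 members detected on both arrays, 6 of them lower. Markers of other cell types were lower beside them, with medians of -1.26 for neutrophils, -0.95 for fibroblasts and -0.78 for endothelium.

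**Figure D2:**
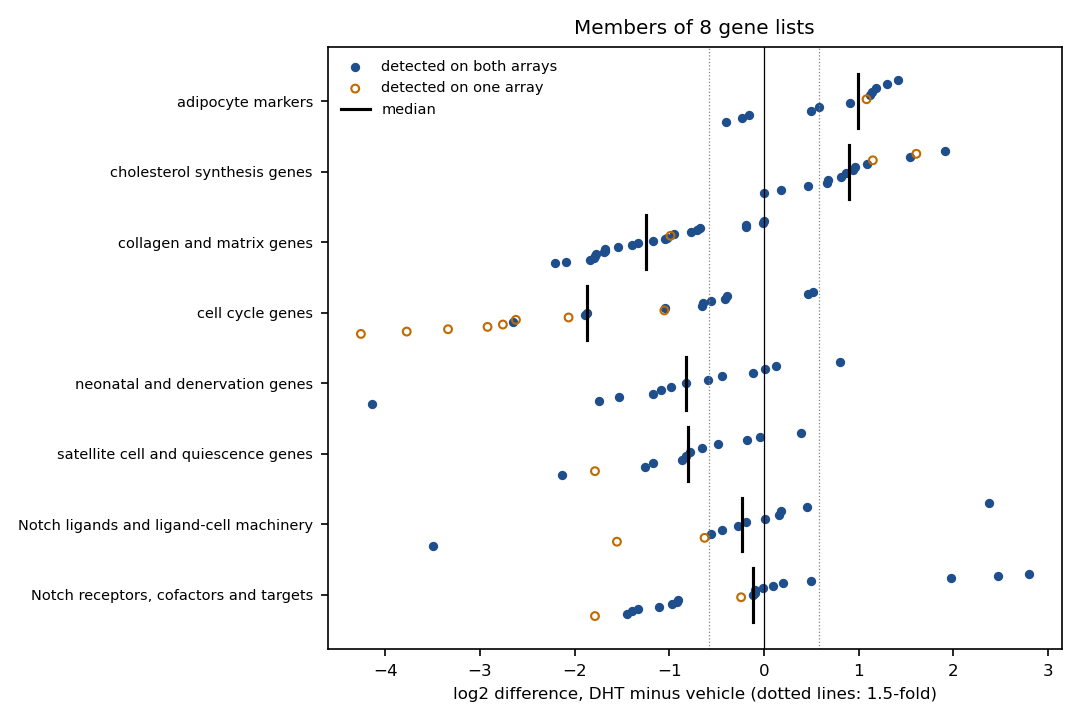
Log2 difference, DHT minus vehicle, of each measured member of 8 gene lists, 1 point per gene. Filled points were detected on both arrays and open points on 1 array, bars are list medians, and dotted lines mark 1.5-fold. The cell cycle members spread from -4.26 to 0.52, and Mib1 (2.38) lies far to the right of the other ligand list members, as do Heyl (2.80), Hey1 (2.47) and Hes1 (1.98) of the other receptors, cofactors and targets.

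Extracellular matrix genes were lower together. The collagen genes Col15a1 (-2.21), Col4a1 (-2.09), Col1a2 (-1.84) and Col5a2 (-1.80) were between 3.47-fold and 4.63-fold lower on the DHT array, Col5a2 2.22-fold uncorrected. Of the 24 measured collagen and matrix genes, 20 were lower and 0 higher at 1.5-fold, 15 of the 20 by 2-fold or more, with a median of -1.25, below all 10000 random lists. The 13 fibroblast and fibro-adipogenic progenitor markers had a median of -0.95, also below all random lists, with 8 lower, among them Cd248 (-1.14) and the collagens Col1a1 (-1.77) and Col3a1 (-1.54), and with the actin-severing gelsolin, Gsn (1.64, 1.80-fold uncorrected), higher.

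Blood vessel markers were lower as well. The endothelial cadherin Cdh5 (-1.78), the receptor Tie1 (-1.36, 1.62-fold uncorrected) and the surface proteins Emcn (-1.25) and Esam (-1.22) led the 14 endothelial markers, whose median was -0.78, with 8 lower and 1 higher. The 12 smooth muscle and pericyte markers had a median of -0.54, with 6 lower, among them the potassium channel Kcnj8 (-1.25), Mcam (-1.22) and the smooth muscle actin Acta2 (-1.18), and 2 higher. The receptor Notch3, counted among the Notch genes, is also a pericyte marker.

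Hormone response genes went in both directions. Fkbp5, a chaperone induced by steroid hormones, was 5.33-fold higher (2.41) on the DHT array, and the small GTPase Rhou 2.68-fold higher (1.42). Of the 18 measured androgen response genes, 5 were higher and 3 lower at 1.5-fold, including Ndrg2 (0.97) and Aldh1a3 (-0.98). Igf1 (0.25), Smox (0.55) and Odc1 (-0.34) were under 1.5-fold, though the 5 Smox probes ran from 0.55 to 0.96. The list median of 0.23 lay just above the random range, at percentile 97.57, and inside it under 8 of 10 alternatives.

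The 22 glucocorticoid response genes, which share Fkbp5 with the androgen list, had a median of 0.54, at percentile 100 of the random lists. Glutamine synthetase, Glul, was 4.88-fold higher (2.29, and 2.64-fold uncorrected) and Fkbp5 5.33-fold higher, and 10 members were higher in all. Pdk4 (-4.22) and Angptl4 (-3.62), genes that also respond to fatty acids through PPAR receptors, were among the 3 lower members. Clock genes had a median of 0.41 over 13 members, at percentile 99.7, with 4 higher and 1 lower, led by Nfil3 (1.23), the clock output gene Dbp (-0.93), Arntl (0.87) and Bhlhe40 (0.68).

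The 20 atrophy, autophagy and ubiquitin ligase genes had a median of 0.20, inside the random range, with 3 higher, Becn1 (0.73), Map1lc3b (0.73) and Bnip3, and 0 lower. Bnip3 was not well above background on the vehicle array, and its bound was 1.15-fold. The 17 growth factor and anabolic genes had a median of -0.15, with Smad3 (0.85) and the activin receptor Acvr2b (0.66) higher and 4 lower, among them Igf2 (-0.69) and Irs2 (-0.69). Of 9 polyamine genes, with a median of -0.05, Amd2 was 4.02-fold higher, or 2.39-fold without background correction, and Sat2 (-0.94) lower. Amd2 belongs to a family of near-identical copies, and the array had no probe named for Amd1. Myostatin, Mstn, was detected on neither array.

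Lipid genes separated by pathway. Cholesterol synthesis genes were higher, with Sqle 3.78-fold higher (1.92, 2.40-fold uncorrected), Lss at least 2.48-fold (1.49-fold uncorrected), Cyp51 2.92-fold (1.55, 1.81-fold uncorrected) and Sc5d at least 2.12-fold (1.33-fold uncorrected). Of 14 measured members, 11 were higher and 0 lower at 1.5-fold, with a median of 0.90, at percentile 100. Without background correction 5 were higher, with a median of 0.42. In contrast, the 22 fatty acid oxidation and PPAR target genes had a median of -0.32, at percentile 0.18, with 7 lower and 1 higher. Pdk4 was 18.6-fold lower, Angptl4 12.3-fold (7.50-fold uncorrected), the mitochondrial carrier Ucp3 at least 10.1-fold (3.65-fold uncorrected) and the lipid droplet protein Plin5 2.98-fold (-1.58, with its other probe at -0.81).

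Adipocyte markers were higher on the DHT array. Adiponectin, Adipoq (1.42), leptin, Lep (1.30), the lipid droplet gene Cidec (1.19) and the desaturase Scd1 (1.14) led the 12 measured markers, of which 8 were higher and 0 lower, with a median of 1.00, at percentile 100, or 0.84 with genes detected on 1 array at their bounds. Several of the genes with the largest positive differences are abundant in fat, among them Cyp2e1, Ces1d, Cdo1, Hp and G0s2.

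Of 14 glycolysis genes, 3 were higher and 0 lower, with the glucose transporter Slc2a1 (1.63), hexokinase 2, Hk2 (1.44), and Pgam1 (0.63). Their median of 0.24 was inside the random range, and outside it under 3 of 10 alternatives. The 32 oxidative phosphorylation genes had a median of 0.12, inside the range, with Ndufa4 (0.95) the only member past 1.5-fold. Signals above 40000 on both arrays were reached by 7 of the glycolysis genes and 9 of the oxidative phosphorylation genes.

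Markers of blood cells moved apart from each other. The neutrophil granule genes Ltf (20.1-fold, 7.17-fold uncorrected), Camp (8.47-fold, 4.31-fold uncorrected), Mpo (at least 3.70-fold, 2.04-fold uncorrected) and Ngp (at least 3.66-fold, 2.02-fold uncorrected) were lower, and 10 of the 11 neutrophil markers were lower at 1.5-fold, with a median of -1.26, below all 10000 random lists. Without background correction 6 were lower. Of the 8 lymphocyte markers, the T cell genes Cd8b1, Cd3d and Cd3g were detected on the DHT array alone, at least 3.75-fold (2.08-fold uncorrected), 2.46-fold and 2.19-fold higher. Thy1 (-2.06) was lower, and so was the B cell precursor gene Vpreb1, at least 2.13-fold. The lymphocyte median of -0.51 lay inside the random range, and was 0.07 over 10 members with a detection p under 0.05. The 3 markers detected on both arrays had a median of -1.44, which stood apart, as did the whole list against random lists not matched on expression.

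The 7 erythroid markers had a median of 0.51, at percentile 98.9, with the haem synthesis genes Fech (1.30) and Alas2 (0.71) and the globin Hbb-b2 (0.97) higher and the membrane transporter Slc4a1 (-1.84) lower. The 13 macrophage and monocyte markers had a median of -0.17, inside the range, with Mrc1 (-0.60) and Cx3cr1, at least 1.53-fold, lower. Without background correction 0 macrophage markers passed 1.5-fold. Interferon response genes had a median of 0.08 over 17 members, with Ifi27l2a (1.61) higher and Gbp3 (-0.94) and Bst2 (-0.78) lower.

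The 16 immediate early genes had a median of -0.10, with 5 lower, led by Jun (-1.43) and Fos (-0.78), and 3 higher, among them Zfp36 (0.86). One of the 3 Ccn1 probes was higher (0.13), against -0.92 for the probe used. The 18 heat shock and unfolded protein genes had a median of 0.15, with the asparagine synthetase gene Asns (1.17) and Hsph1 (0.59) higher and Hsp90b1 (-0.66) lower. The 18 ribosomal protein genes had a median of -0.18, just below the random range, with Rpl3 (-0.79) and Rpl22 (-0.62) lower, and the median was -0.016 under median scaling.

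Markers of nerve and tendon did not stand apart. The 7 Schwann cell markers had a median of 0.16 with 0 members past 1.5-fold, and the 8 tendon and cartilage markers a median of -0.27, or 0.01 with genes detected on 1 array at their bounds. Of the skin list only Krt10 (0.14) and Trp63 (-0.07) were detected, too few for a median. The Y-linked genes Eif2s3y (0.17), Kdm5d (0.05) and Uty (-0.11) were detected on both arrays, Xist on neither, and no probe was named for Ddx3y. Both arrays therefore held male RNA, with Y-linked differences under the probe-to-probe SD of 0.25. An undetected Xist does not by itself exclude some female RNA.

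Of the 34 lists with a median, 18 stood apart, 6 high and 12 low, where 1.7 would by chance if the genes of a list varied independently. Genes of a list can vary together between any 2 samples, and some lists share members. How many lists would stand apart between untreated animals was not measured. Of those 18, the androgen and ribosomal lists lost that place under some alternatives and 16 kept it under all 10. Some counts of members at 1.5-fold also depended on the background correction: without it, 1 androgen response gene and 2 growth factor genes were lower, and 1 atrophy gene and 1 immediate early gene were higher.

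**Figure D3:**
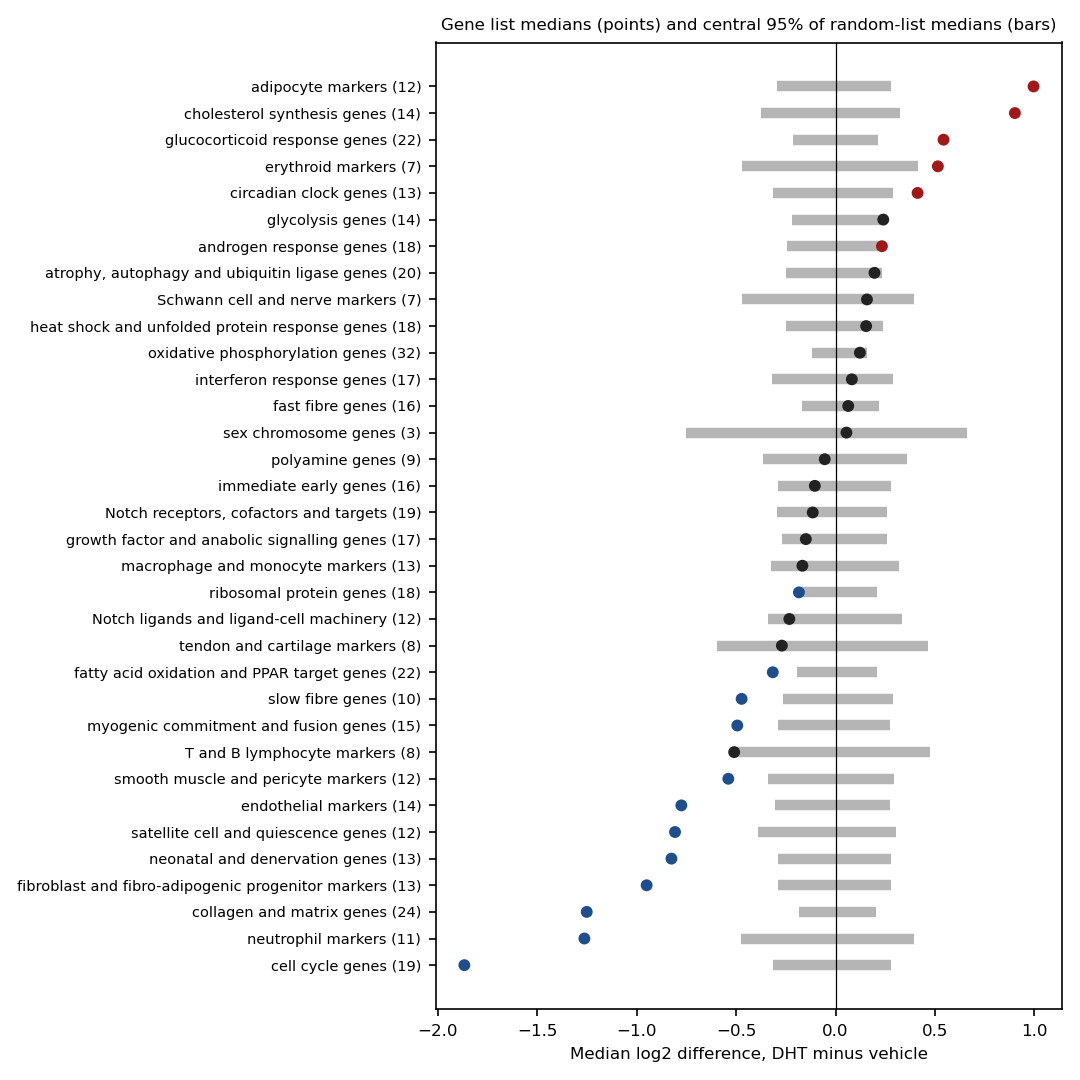
Median log2 difference, DHT minus vehicle, of 34 gene lists (points) and the central 95% of medians of 10000 random lists matched on expression (bars), with the number of measured members in brackets. Red points lie above the bars, blue points below and black points inside. Adipocyte markers lie at 1.00 and cell cycle genes at -1.87, or at 0.84 and -1.04 with genes detected on 1 array at their bounds.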

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

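No test was run for the values given here, and no biological explanation was tested. The comparisons of the report use named probes, so the 1719 probes without a gene name were left out of them. Of these, 694 were detected on at least 1 array, 28 of them at least 2-fold higher and 55 at least 2-fold lower on the DHT array by their measured values. Some of these were not well above background on 1 array and have only a bound, and of the 615 detected on both arrays 16 were higher and 32 lower by 2-fold. Among the unnamed probes detected on both arrays, ILMN_2759484 had the largest positive log2 difference, 3.60, with deposited signals of 403 on the vehicle array and 2867 on the DHT array. The brighter probe ILMN_2835423 followed with 2.08, from a signal of 6787 on the vehicle array to 24459 on the DHT array.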

How the results depend on the processing

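The alternatives were fixed before the data were examined, except for leaving out the probes above 40000 on both arrays, which was added later. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out and no other split of the samples was possible. At 1.5-fold, 2022 to 2799 genes passed with median scaling, cyclic loess, an offset of 50, detection on both arrays, a detection p under 0.05, the mean of a gene's probes, or without the probes above 40000. Without background correction 1268 genes passed (564 higher, 704 lower; 156 and 231 at 2-fold), and with the deposited values 1338 (595 higher, 743 lower; 166 and 244 at 2-fold). All genes of these 2 counts were also among the 2574 of the chosen setting, in the same direction. These settings leave the background in the signal, which shrinks folds of dim genes. At 2-fold, 960 genes passed. Median scaling moved the share of higher genes from 45.8% to 51.0%, and cyclic loess to 42.3%. Among 164 named genes, 0 of those past 1.5-fold changed direction, and changes of direction of smaller differences were not counted. Without background correction 86 of the 164 moved by more than the probe-to-probe SD, with the deposited values 82 and with an offset of 50 49, all toward 0. With the mean of a gene's probes 13 moved, 9 of them toward 0. Of the 18 lists that stood apart, 16 did so under all 10 alternatives. The androgen median was inside the random range without background correction (0.19), under median scaling (0.25), under cyclic loess (0.20), with the deposited values (0.20), and, at a median of 0.23, with detection on both arrays, a detection p under 0.05, without the probes above 40000, and against unmatched random lists. The ribosomal median was inside it under median scaling (-0.016), cyclic loess (-0.18), the mean of a gene's probes (-0.16) and unmatched random lists (-0.18). The cause of these moves was not tested. Signal over background limits the dim genes: 512 genes detected on the vehicle array alone and 332 on the DHT array alone have bounds only.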

Other observations

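Of the tests below, only the comparison of the Notch genes with equally dim probes was fixed before its result was seen, and its allowance for how those genes were picked came later. All other tests, and the 6 gene lists added to those of the report, were chosen afterwards, from genes some of which had been seen.

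Imprinted growth genes, expressed from a single parental copy and abundant in fetal and early postnatal tissue, were lower on the DHT array. Of 10 measured, 8 were lower and 0 higher at 1.5-fold, with a median of -1.17, below all 10000 random lists. The largest differences were those of Dlk1 (11.3-fold), Mest (6.92-fold), Cdkn1c (4.40-fold) and Peg3 (3.12-fold, 1.96-fold uncorrected), while Gnas (0.06) and Impact (0.12) lay near 0. Genes of unfused or recently fused fibres had a median of -1.13 over 12 members, 9 lower and 0 higher, among them nestin, Nes (-1.38), and the embryonic light chain Myl4 (-0.88). Most of its members, among them Myh8, Mymk, Chrng and Myog, also stand in lists of the report, as do the imprinted Dlk1, Cdkn1c and Igf2.

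Replication-dependent histone genes did not move together. The 6 genes H2ac22, H2ac10, H2ac24, H2ac12, H2ac11 and H2ac15 were lower, the first by 24.7-fold (15.3-fold uncorrected), while H2ac6 (0.24) and H2ac8 (-0.17) were not, and the linker histone H1f2 (0.89) and H2bc14 (0.61) were higher. The 15 measured histone genes had a median of 0.02, inside the random range. The H2A copies are nearly identical, so their probes do not count as separate genes with certainty. Of the liver and plasma protein list, 3 genes were measured and all 3 were higher, Apoc3 at least 2.17-fold (1.44-fold uncorrected), Rbp4 2.30-fold (1.41-fold uncorrected) and Trf 1.99-fold, with a median of 1.20.

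The first pattern weighed is the higher Mib1, Hey1, Heyl and Hes1. The lowest of the 4 lay at percentile 99.5 among named probes with a vehicle signal within 10% of its own. However, the 4 were picked as the highest of 31 measured Notch genes. For the single highest of 31 that choice would call for percentile 99.9194, which 1 of the 4 passed. Such percentiles rank a gene among all differences, real ones included, so they cannot set noise apart. Noise of dim signals stays open for Mib1, Hey1 and Heyl. Hes1 was not dim, with deposited signals of 717 on the vehicle array and 2016 on the DHT array, and was 3.31-fold higher uncorrected. Over all 31 genes, 4 lay above the central 95% of probes with a vehicle signal within 10% of their own and 3 below it, where 0.775 would on each side by chance. Background correction alone does not make the difference, as the smallest of the 4 was 1.28 on the log2 scale without it, and more vessel cells in the DHT sample, which carry Hey1 and Heyl, would raise their markers, but 25 endothelial and pericyte markers had a median of -0.74. A response to DHT may remain as a hypothesis, for which the Notch target Nrarp (-0.92, percentile 6.43 of such probes) gives no backing, and with 1 array per group it was not separated from a difference between the animals.

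The second pattern is the fat and lymph node genes among the largest differences on the DHT array. More fat tissue in that sample could raise them, and as the only cause it would raise fat-restricted genes as much. The median of Cyp2e1, Ces1d, Cdo1, Hp, Adig, Mrap and G0s2, with Cyp2e1 at its bound, exceeded that of Adipoq, Lep, Plin1, Cidec and Cidea by 1.77 on the log2 scale. The 7 genes were chosen for the size of their differences, which by itself favours such a gap, so it does not decide on this cause. Lymph node tissue in the sample could account for Glycam1, Cd209b and Cxcl13, and 20 lymph node and lymphocyte genes, 15 of them also detected on the vehicle array, had a median of 0.61, with 11 higher and 0 lower, but most had been seen when the list was written. The 6 not seen before had a median of 0.34, inside the random range, and their brightest, Laptm5 and Lsp1, lay at -0.34 and 0.63. The T and B lymphocyte list fixed beforehand had a median of -0.51, with 3 higher and 4 lower, among the latter Thy1 (-2.06). The 3 higher were the T cell genes Cd8b1, Cd3d and Cd3g, detected on the DHT array alone. They are left out of the 3 members detected on both arrays, whose median was -1.44. Members of this list went both ways, so its medians do not count against lymph node tissue. Lymph node tissue in the sample stays undecided. More fat as the only cause or as part of it, a change within fat cells and an effect of DHT stay open as well.

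The third pattern is the lower cell cycle, matrix and neonatal genes, beside which neutrophil markers (median -1.26) and endothelial markers (-0.78) were lower too. The choice among the normalizations tried did not make these groups lower. The highest of the 3 list medians under median scaling, cyclic loess and the deposited values was -0.70. The deposited values are themselves quantile normalized. The median difference of all genes was 0.037 under median scaling and -0.037 under cyclic loess, so the comparison was a weak test of this cause. Fewer fibroblasts as the whole cause of the lower matrix genes would lower collagens and other fibroblast markers alike. The collagen median lay below that of 11 other fibroblast markers by a difference of -1.09 (-1.77 against -0.68), and the lowest of the 11 was -1.14. Other cells can make genes of either set, and the contrast was chosen after values were seen, so it does not settle the number of fibroblasts. The labels give both groups the same age at injection, 10 days, and the same 24 h to sampling. A sample from animals more mature at that age could lower all 3 groups together with the imprinted growth genes, whose median was -1.17. Since each group had 1 array, growth stage and the injection cannot be told apart. The effect of DHT itself stays open as well, and was not tested apart from growth stage.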
